A study of Pimephales promelas with 14 samples.

How the data were processed

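Liver RNA of fathead minnow (Pimephales promelas), a small freshwater fish used in reproduction tests, was measured on 14 one-colour Agilent arrays. Per the labels, each array carried Cy3-labelled RNA pooled from 6 fish of 1 sex that had been held in cages in 1 stream for 21 days. The label descriptions also speak of a reproduction cycle of another length, and the 21 days of the source names are used here. Streams were grouped by the submitters into a high and a low class of egg production, which gave 4 high female, 3 low female, 4 high male and 3 low male arrays. Each array stands for 1 stream and sex. A pool hides the spread between fish. Per the series' design text, 1 creek contributed to both classes in different years, and 1 low stream lost 6 fish shortly before the end; which replicate that was is not given in the sources used here.

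The scanner intensity values were deposited by the authors as Feature Extraction output, version 9.5.3.1 per the file headers and 9.1 per the submitters' processing notes. Per the file headers each of the 15208 probes is a 60-base sequence on 1 spot, and the processed signal is a background-corrected intensity on a linear scale. Well above background, saturation and outlier flags are other columns of those deposited files. A deposited table of the authors' processed values holds values on a log2 scale for the same probes, as judged from slopes of 0.849 to 1.07 on the log2 signal of the best matching array. Its centring is not given in the sources used here. All of its 14 columns had their highest correlation with another array than the labelled one, so it was used only as an alternative and only as labelled. In order of the replicate numbers as labelled, its column medians were -0.52, -0.34, 0.19 and -0.54 for high females, -0.11, 1.08 and -0.64 for low females, 2.64, -0.63, -0.16 and -0.90 for high males and 0.12, 1.55 and 0.07 for low males.

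No probe was given a gene name with the sources used here. The description of all 15208 probes is empty or unknown, and 0 of them matched the gene table supplied for the species by identifier. The probe sequences were not searched against other sequences. Probes are therefore reported by identifier and sequence, with at most 2 that rose and 2 that fell per comparison. The planned gene and marker lists were not tested, and the check of the labels through a known sex-specific gene was not made.

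The processed signal was put on the log2 scale and each array's 75th percentile was subtracted. On most arrays under 50% of the probes were detected, so the percentile was taken over the 236 probes well above background on all 14 arrays. Spots flagged as outliers were set to missing, and saturated spots were kept. A probe was kept if it was well above background on every array of at least 1 of the 4 groups, which left 5914 probes. This was met by 1934 probes in high females, 4457 in low females, 4561 in high males and 388 in low males. Probes bright only in low males could thus hardly enter, so the filter favours calls lower in low males wherever that group enters. The 4 group means were fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). High was set against low in each sex and averaged over sexes, female against male in each class and averaged over classes, and the interaction was tested, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. Probes with no unflagged spot in a group were not tested where that group entered, which left 5906 probes in 5 of the contrasts. The named probes are the 2 with the highest and the 2 with the lowest log2 difference among those called, filled up by unadjusted p where fewer passed. These contrasts, the filter and most alternatives were fixed before the data were examined. The naming rule fixed with them took more probes per direction and needed gene names, and was shortened because the files hold none. Where a probe was not well above background on any measured array of a group, the fold is given as a lower limit. That limit sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest well above background signal. It is not strict where an array of the bright group was itself not well above background. No such limit is given against low males. On low male replicates 2 and 3, 76.7% and 99.5% of the spots not well above background had a higher processed signal than the lowest spot that was, against at most 10.3% on any other array, so the flag did not follow the signal there.

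For each array, the share of spots well above background was computed in a window of 15 by 15 spots around every spot. A spot was taken to lie in a low-detection area where that share was under 0.5 of the array's own 90th percentile of the share. This measure was devised after the uneven detection had been seen, and it is itself made from detection around the spot. Array measures were compared with exact permutation tests, two-sided, with p taken as 2 times the smaller tail. Counting splits by the size of the difference alone, the definition used at first, gives smaller values for groups of unequal size. The test as used cannot give a p under 0.0571 for 4 arrays against 3, nor under 0.1 for 3 against 3.

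The fit was tested on simulated data with the real probe means, residual spreads and missing values, in which 50 of 5914 probes each were changed by 4, 16, 64 and 256-fold. For high against low females, 2.0% of the 4-fold, 56.0% of the 16-fold and 92.0% of the 64-fold changes were recovered, with 10 unchanged probes called. For high against low males the shares were 6.0%, 50.0% and 82.0%, with 3 unchanged probes called. The simulation gave every array the same spread, which the real arrays did not have.

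Alternatives were quantile normalization, median centring, normexp background correction (offset 50) with quantile normalization, the authors' table, other filters on dim probes, array weights, the stream or replicate number as a block, the arrays of 1 sex alone and leaving out each array. Others were added after seeing the data: the percentile over all probes, a floor, leaving out low-detection areas, and leaving out sets of arrays that had them. The tests of explanations in the closing section were also chosen after the results were seen. For the probes higher in females on high male replicate 3, an unadjusted p under 0.01 was used to choose probes after a stricter limit had left a set empty. The tests of weaker labelling, of a higher array scale, of wrong scanner labels, of female RNA in a pool and of low-detection areas on high male arrays were revised after a first version had been run. Per the names of the scanner files, same-numbered female and male arrays of a class come from the same stream, in 7 of 7 streams. The deviations of these pairs from their group means correlated over 0.1 in 1 of 7, and 2 of 7 female arrays correlated best with the male array of their own stream. Across classes, the shared number marks no pairing in the labels, and no fit modelled the creek that contributed to both classes. All males were on 1 slide and in 1 scan and all females on the other, so slide, scan and sex cannot be told apart, and a fit with the slide as a term could not be made for the sex contrasts. The high against low contrasts within a sex lie within a slide, where a slide term equals the sex term already in the group means. Low arrays lay in columns 3 and 4 of each slide and high arrays in columns 1 to 3, so class goes with position on the slide. Both arrays of each stream lay at the same row and column of their slides. Stream and position therefore cannot be told apart, and a stream block is also a position block. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.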

Results

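The study asked how hepatic gene expression differs between sexes and between streams where caged fathead minnows laid many or few eggs. The arrays differed in how much they detected. The share of the 15208 probes well above background was 36.02% ± 15.9 (SD, n = 4) in high females, 38.8% ± 8.45 (SD, n = 3) in low females, 48.4% ± 9.32 (SD, n = 4) in high males and 15.6% ± 7.04 (SD, n = 3) in low males. The low male arrays detected 14.1%, 23.2% and 9.38% of probes, and the lowest high male array 34.7%. The exact two-sided permutation p between high and low males was 0.0571, the smallest that 4 arrays against 3 allow, and 0.196 after Benjamini-Hochberg adjustment over 12 such tests. Spike-in signal over background, from RNA added at labelling, was 11.2 ± 7.99 (SD, n = 3) in low males against 77.7 ± 30.3 (SD, n = 4) in high males. Detection was not even over the surface: 67.9%, 50.5% and 74.1% of spots on the 3 low male arrays lay in low-detection areas, as did 31.6% on high male replicate 2, 27.1% on high female replicate 1, 19.3% on high female replicate 4 and 7.01% on high female replicate 2. The other arrays had at most 2.14%. The number of arrays limits the precision of all comparisons.

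**Figure D1:**
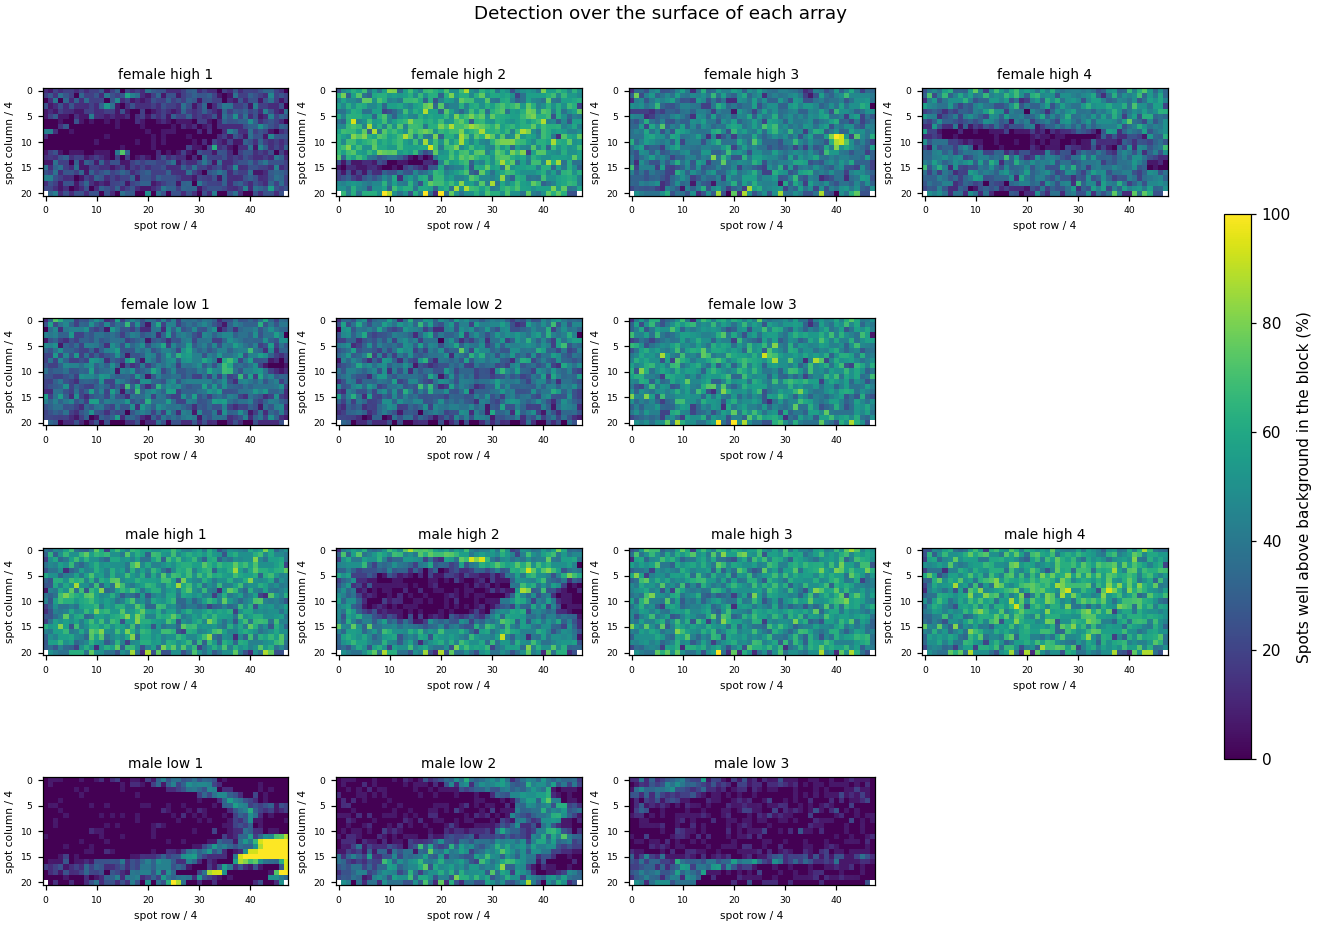
Share of spots well above background (%, colour) in blocks of 4 by 4 spots over the surface of each of the 14 arrays, with spot row and column divided by 4 on the axes. Dark areas cover most of the 3 low male arrays, where 67.9%, 50.5% and 74.1% of spots lay in low-detection areas, and low male replicate 1 also has a bright patch where nearly every spot was well above background.

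The first comparison asked whether high and low streams differed in females. No probe was called: 0 of 5914 passed in limma, and 78 had an unadjusted p under 0.05 where chance alone gives 295.7. UF_Ppr_AF_105830 had a normalized log2 signal of -5.16 ± 0.48 (SD, n = 4) in high and -8.00 ± 0.71 (SD, n = 3) in low females, where it was not well above background (adjusted p = 1.00). The limit gives 1.82-fold, but it counts high female replicate 1, which was not well above background either, and so is not strict. UF_Ppr_AF_103236 was at -5.05 ± 0.29 (SD, n = 4) in high females and -7.72 ± 0.93 (SD, n = 3) in low females, again not well above background there (adjusted p = 1.00). Its limit of 1.96-fold is not strict for the same reason. UF_Ppr_AF_105481 was at -4.78 ± 2.12 (SD, n = 4) in high and -1.76 ± 0.82 (SD, n = 3) in low females, with 1 of the 4 high arrays well above background (adjusted p = 1.00). UF_Ppr_AF_109972 was at -1.06 ± 6.15 (SD, n = 4) in high females, where it was saturated on 2 arrays and in a low-detection area on 2, and at 5.30 ± 0.50 (SD, n = 3) in low females, where it was saturated on 3 (adjusted p = 1.00). None of these passed the test. The median 95% interval of a log2 difference, per probe and not adjusted, reached 1.96 to either side, or 3.89-fold, and in simulated data the test recovered 2.0% of 4-fold and 56.0% of 16-fold changes in this comparison. The 7 female arrays alone, all on 1 slide, also gave 0 calls in limma, with 45 of 4585 probes at an unadjusted p under 0.05.

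The same comparison in males called 716 of 5906 probes, 690 higher and 26 lower in high streams. This split depended on the processing: median centring gave 203 calls, 108 higher and 95 lower, and without a filter on dim probes there were 6096, 992 higher and 5104 lower. The filter itself favours calls higher in high males, since 4561 probes met it there and 388 in low males. UF_Ppr_AF_108387 (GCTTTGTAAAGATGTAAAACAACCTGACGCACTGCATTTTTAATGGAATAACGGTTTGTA) was at 1.91 ± 0.56 (SD, n = 4) in high males and at -7.59 on the only low male array with an unflagged spot, where it was not well above background (adjusted p = 7.31e-05). UF_Ppr_AF_105401 was at 0.51 ± 1.23 (SD, n = 4) in high males and at -8.05 on the only low male array with an unflagged spot, again not well above background (adjusted p = 0.00166). No fold is given for either, and their adjusted p assumes that the lone array varies like the other groups, as it does for 21 of the 716 calls. Those are 51.2% of the 41 probes tested with 1 unflagged low male spot, against 33.7% of 175 called with 2 and 11.2% of 5690 with 3. UF_Ppr_AF_107857 was lower in high males, at -8.09 ± 1.80 (SD, n = 4) against -3.01 ± 2.10 (SD, n = 3), but only 1 array of each group was well above background (adjusted p = 0.0119). UF_Ppr_AF_109714 was called lower in high males (adjusted p = 0.00461) and was not well above background on any male array, so no fold is given. UF_Ppr_AF_107857 lost its call without low male replicate 1 (adjusted p = 0.0533) and UF_Ppr_AF_109714 without low male replicate 3 (adjusted p = 0.0575). The median log2 difference of all tested probes was 0.96, so most probes read lower on the low male arrays in this scaling. Of probes whose spot lay in a low-detection area on none of the low male arrays, 17 of 571 (2.98%) were called, against 115 of 1750 (6.57%) with 1 such array, 307 of 1707 (18.0%) with 2 and 277 of 1878 (14.7%) with 3. With those spots left out and the arrays recentred, a setting added after seeing the data, 28 of 2171 probes were called, 11 higher and 17 lower, and 12 of these were among the 80 called before that could still be tested. The 7 male arrays alone, all on 1 slide, gave 395 calls among 4581 probes.

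**Figure D2:**
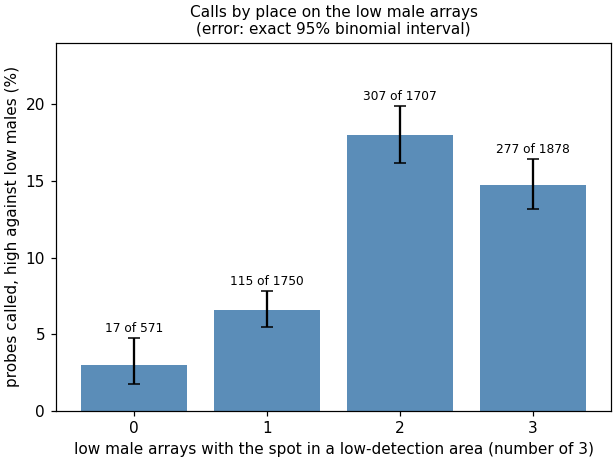
Percent of tested probes called between high and low males (bars, with exact 95% binomial intervals) by the number of low male arrays on which the probe's spot lay in a low-detection area. The share was 2.98% with 0 such arrays and 14.7% with 3. The intervals treat probes as independent.

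Averaged over both sexes, 215 of 5906 probes were called between high and low streams, 211 higher and 4 lower in high. The 2 with the highest difference, UF_Ppr_AF_108387 (adjusted p = 0.00304) and UF_Ppr_AF_105401 (adjusted p = 0.0145), were those named in males. Each rests on 1 low male spot that was not well above background, so no size is given, and UF_Ppr_AF_105401 lost its call without low female replicate 2 (adjusted p = 0.0513). UF_Ppr_AF_109583 was lower in high streams by a log2 difference of -2.88 ± 0.73 (SE; adjusted p = 0.0427), with 1 of 4 high female arrays well above background. UF_Ppr_AF_112923 was lower by -2.71 ± 0.62 (SE; adjusted p = 0.0273), with 2 of 4 high female and 1 of 4 high male arrays well above background. On the 3 low male arrays both probes had their spots in low-detection areas, and their calls were lost in 9 and 8 of the 14 fits that left out 1 array. Without low male replicate 1 the differences were -3.55 and -3.34, and without low male replicate 3 the second was -2.05. The median log2 difference of all tested probes was 0.42. Few probes could enter through low males, so the filter also favours calls higher in high streams. Median centring gave 0 calls in limma, with 533 probes at an unadjusted p under 0.05, and with low-detection areas left out 2 probes were called, both lower in high streams.

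Females were compared with males in the high streams, where no low male array enters the contrast. The low male arrays still enter the shared estimate of the spread and the choice of the probes used for centring. Of 5914 probes 3 were called, all higher in females, and 134 had an unadjusted p under 0.05 where chance gives 295.7. UF_Ppr_AF_115478 (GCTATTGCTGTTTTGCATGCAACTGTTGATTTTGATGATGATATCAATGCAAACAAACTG) was at 2.89 ± 0.70 (SD, n = 4) in females and -4.99 ± 2.57 (SD, n = 4) in males, a log2 difference of 7.88 ± 1.04 (SE, adjusted p = 0.0123), with the 4 female arrays all above the 4 male arrays. High male replicate 3, at -1.16, lay apart from the other high males, and without it the difference was 9.16. UF_Ppr_AF_117573 (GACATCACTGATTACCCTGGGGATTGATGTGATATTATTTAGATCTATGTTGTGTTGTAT) was at 0.38 ± 2.36 (SD, n = 4) in females and -7.25 ± 1.00 (SD, n = 4) in males (adjusted p = 0.0286), a fitted log2 difference of 7.62 ± 1.15 (SE) that includes 1 of the 4 male arrays not well above background. It was 8.51 without high female replicate 1, whose spot lay in a low-detection area, and 6.75 without high female replicate 3, where the call was lost (adjusted p = 0.0951). UF_Ppr_AF_118394, named after its values were seen because the count is small, was at -4.30 ± 0.33 (SD, n = 4) in females and not well above background on the 4 male arrays (adjusted p = 0.0453). The limit puts males 7.45-fold lower, but it counts high female replicate 1, which was not well above background either, and so is not strict. UF_Ppr_AF_115272, chosen after its values were seen, was at 4.92 ± 1.01 (SD, n = 4) in females, saturated on 2 of the 4 arrays, and at -1.80 ± 2.52 (SD, n = 4) in males; it did not pass (adjusted p = 0.159), but did without high male replicate 3 (adjusted p = 0.0356). Among probes lower in females none passed: UF_Ppr_AF_111380 was at 1.57 ± 0.99 (SD, n = 3) against 4.16 ± 0.31 (SD, n = 4), and UF_Ppr_AF_103721, well above background on 1 of the 4 female arrays, at -5.95 ± 3.06 (SD, n = 4) against -1.38 ± 1.77 (SD, n = 4), each with an adjusted p of 0.999. The count ranged from 0 to 3 when single arrays were left out, and was 0 without high female replicate 2 or 3, high male replicate 1 or 4, or low male replicate 3, and it was 0 with low-detection areas left out. Of the 14 fits that left out 1 array, UF_Ppr_AF_115478 lost its call in 5, UF_Ppr_AF_117573 in 10 and UF_Ppr_AF_118394 in 12. With the stream as a fixed block the count was also 0 in limma, with 2.08% of the probes at an unadjusted p under 0.05. Sex, slide and scan cannot be told apart in any of these values.

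**Figure D3:**
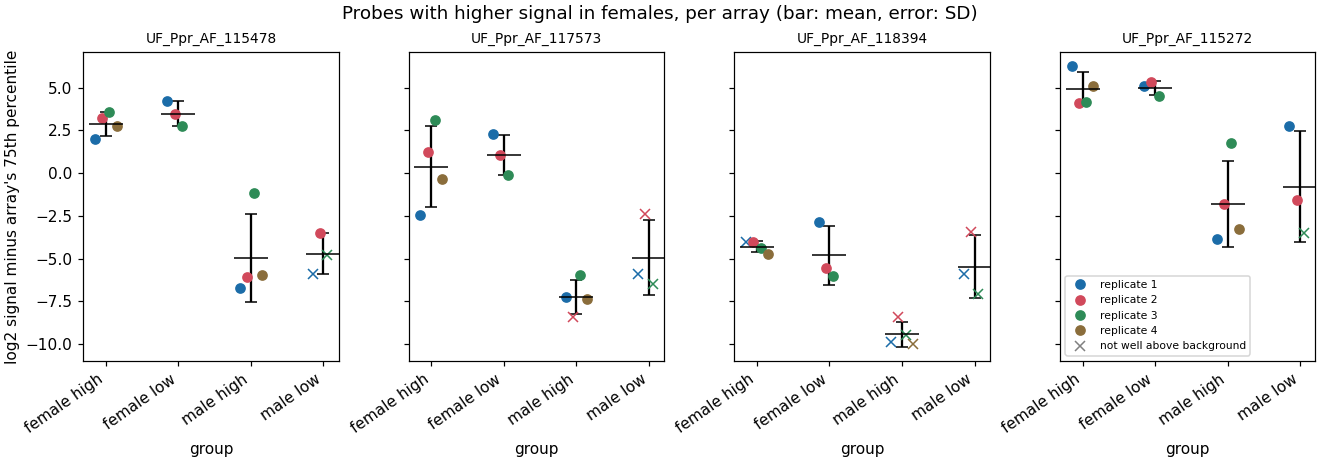
Normalized log2 signal (log2 signal minus the array's 75th percentile) of 4 probes on each array by group, with the mean (bar) and SD (error bar); crosses mark spots not well above background. UF_Ppr_AF_115478 lay at -1.16 in high male replicate 3 and at -6.71, -6.08 and -5.99 in the other high males.

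Averaged over classes, 276 of 5906 probes were called between females and males, 272 higher and 4 lower in females. With the stream as a fixed block 4 probes were called, all higher in females, and with median centring 19. UF_Ppr_AF_115478 differed by 8.04 ± 0.79 (SE, adjusted p = 3.53e-04) on the log2 scale, and by 8.66 without high male replicate 3, with 1 of 3 low male arrays well above background. UF_Ppr_AF_117573 was also called (adjusted p = 0.00118), but was not well above background on any low male array, so no size is given. UF_Ppr_AF_103721 was lower in females by a log2 difference of -3.99 ± 1.00 (SE, adjusted p = 0.0362), a difference against values near background, since it was well above background on 1 of 4 high and 1 of 3 low female arrays. UF_Ppr_AF_114856 was lower by -2.99 ± 0.66 (SE, adjusted p = 0.0194). Of the 14 fits that left out 1 array, UF_Ppr_AF_103721 lost its call in 9 and UF_Ppr_AF_114856 in 3, and the former was at -4.76 without high female replicate 4. The median log2 difference of all tested probes was 0.61. Few probes could enter through low males, so the filter also favours calls higher in females. The count was 32 with low-detection areas left out, 15 higher and 17 lower in females.

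In the low streams 641 of 5906 probes were called between the sexes, 608 higher and 33 lower in females. UF_Ppr_AF_108387 was at 2.07 ± 0.35 (SD, n = 3) in low females and at -7.59 on the only low male array with an unflagged spot, so the adjusted p of 1.40e-04 again assumes that array to vary like the other groups. UF_Ppr_AF_107655 was at 2.61 ± 0.97 (SD, n = 3) in low females and at -5.70 ± 0.87 (SD, n = 3) in low males (adjusted p = 4.87e-04), where it was not well above background and lay in a low-detection area on the 3 arrays, so no fold is given. UF_Ppr_AF_104171 was lower in females, at -6.62 ± 0.76 (SD, n = 3) against -0.98 ± 1.32 (SD, n = 3; adjusted p = 0.0382), but was well above background on 1 of the 3 female arrays. UF_Ppr_AF_100641 was also lower in females, with 2 of 3 female arrays well above background, at -5.87 ± 1.63 (SD, n = 3) against -0.55 ± 3.11 (SD, n = 3; adjusted p = 0.0165). Of the 14 fits that left out 1 array, the call of UF_Ppr_AF_104171 was lost in 5 and that of UF_Ppr_AF_100641 in 2. The median log2 difference of all tested probes was 1.15. Here too the filter favours calls higher in females, since few probes could enter through low males. Median centring gave 220 calls, 98 higher and 122 lower in females, and leaving out low-detection areas gave 69, 25 higher and 44 lower. With the stream as a fixed block 265 were called.

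The test of whether the class difference itself differed between sexes called 169 of 5906 probes, 4 above and 165 below 0, where a value below 0 means a smaller high minus low difference in females than in males. UF_Ppr_AF_108387 was called below 0 (adjusted p = 0.00398) from 1 unflagged low male spot that was not well above background, so its size was not measured. UF_Ppr_AF_111384 had a difference of -8.42 ± 1.20 (SE, adjusted p = 0.00528), resting on 1 unflagged low male spot in a low-detection area. UF_Ppr_AF_107857 was called above 0 (adjusted p = 0.0341), but was well above background on 4 of 4 high female, 0 of 3 low female, 1 of 4 high male and 1 of 3 low male arrays, so its size was not measured. UF_Ppr_AF_109244 had 4.41 ± 1.11 (SE, adjusted p = 0.0466), with 1 of 4 high female, 1 of 3 low female, 4 of 4 high male and 2 of 3 low male arrays well above background. Both rest on groups near background, and their calls were lost in 8 and 10 of the 14 fits that left out 1 array. The median over all tested probes was -1.07. Few probes could enter through low males, so the filter also favours values below 0. With low-detection areas left out 1 probe was called, and median centring and the stream as a fixed block each gave 0 in limma, with 811 and 887 probes at an unadjusted p under 0.05.

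The deposited value table was set against the scanner arrays, with each probe centred on its median over arrays. Each of the 14 columns had its highest correlation over probes, 0.887 to 0.993, with a different array than the labelled one, and no array was matched by 2 columns. The correlation with the labelled array ran from -0.457 to 0.333. All other values here follow the labels of the scanner arrays, and the match itself does not show whether the labels of the table or those of the arrays are out of order. Probes are not independent replicates, so these correlations carry no test.

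**Figure D4:**
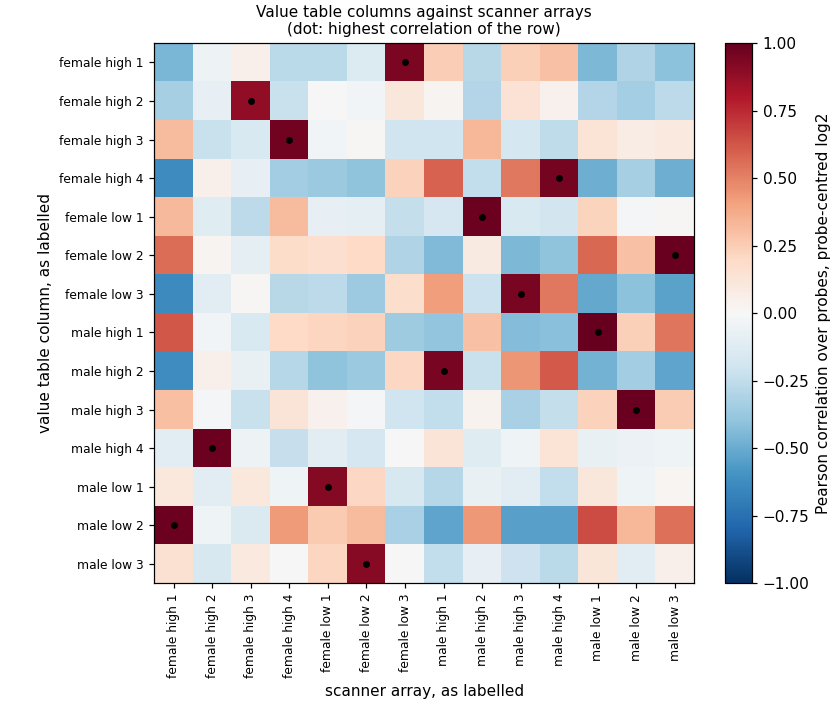
Pearson correlation over probes (colour) between the columns of the deposited value table and the scanner arrays, both as labelled and centred per probe; dots mark the highest value of each row. The 14 dots, at 0.887 to 0.993, all lie off the diagonal.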

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

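The tests of the 3 patterns weighed here were all chosen after the results were seen, and 5 of them were revised after a first run, while the counts over other splits of the samples were planned, except for those that exchange the sexes within streams or the class of whole streams. Of 47 sets of 4 values, 5 had a value far from the others, where chance gives about 2.35. They are UF_Ppr_AF_107857 in high female replicate 1 (-1.42), the share of spots in low-detection areas on high male replicate 2 (31.6%), UF_Ppr_AF_105401 in high male replicate 3 (-1.32), UF_Ppr_AF_115478 in high male replicate 3 (-1.16) and UF_Ppr_AF_104171 in high male replicate 4 (-9.83). The test of the interaction called 169 probes, among them UF_Ppr_AF_109244 (4.41), UF_Ppr_AF_111384 (-8.42), UF_Ppr_AF_107857 and UF_Ppr_AF_108387. The fitted values of the last 2, 7.08 and -9.49, are no measured sizes, since a group had no array well above background. The test called 0 with median centring or the stream as a fixed block and 1 with low-detection areas left out, and other splits of the samples do not exclude chance.

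The calls between high and low males followed the place of the spot. Where the spot lay in a low-detection area on all 3 low male arrays, the share called was 4.95 times that with none. This goes with poor detection over areas of the arrays, though the share was highest, 18.0%, with 2 such arrays and not with 3. The areas are themselves made from detection. On low male replicates 2 and 3, 76.7% and 99.5% of undetected spots had a higher signal than the lowest detected one. Low male replicate 3 also had the highest median processed signal, 217, against 68.3 on high female replicate 2, the next highest. Low detection there was therefore not shown to be a loss of signal. Weaker labelling of the low male arrays as a whole goes with their low spike-in signal over background and may contribute. Their median processed spike-in signal was 55.2, 934 and 947 on replicates 1 to 3, under the high males (1661 to 9828). High female replicates 1 and 4, however, had 287 and 463. Weaker labelling would give like shares everywhere. This was tested with areas from the neighbouring spots alone, over probes well above background on every high male array and not used for centring. With 0 such areas 3.59% were called (interval up to 5.69%) and with 3 such areas 28.4% (interval from 25.4%). That argues against weaker labelling as the whole cause, although among the dimmest tertile of probes both intervals overlapped. The intervals treat probes as independent, which neighbouring spots on the same arrays are not, so they understate the uncertainty. Egg production class stays open, since 2.98% of probes were still called with 0 such areas, and the data cannot separate a remaining class effect from a weak signal beyond the mapped areas. No other of the 35 splits of the 7 male arrays gave as many calls as the 716 found. That share, 2.86%, is the smallest that 35 splits allow, so it argues against chance without excluding it. A split that exchanged low replicate 2 with high replicate 2, both with large low-detection areas, gave 685, so the count alone does not single out the class.

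The columns of the deposited value table may stand in another order than their labels. All 14 columns matched the array at the same place when the scanner files are sorted by name, while the samples are listed in another order. Wrong labels on the scanner files cannot be told apart from this: 2 probes parted the 7 female from the 7 male arrays by at least 4-fold under the scanner labels and 0 under the labels of the table, but the sexes lay on different slides, and a slide difference would give the same. The names of all 14 scanner files give the labelled sex, and in 7 of 7 streams named there both arrays share class and number. Wrong labels on the arrays would thus need misnamed files too: of the 7 arrays female by the table's labels, 3 have files named female. File names are no measurement. No biological explanation was tested, and no column was reassigned.

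High male replicate 3 lay above the other high males for many probes higher in females: of 74 such probes, chosen without this array, 66 were above, with a median log2 shift of 1.33, against 0.13, -0.06 and -0.00 for replicates 1, 2 and 4 treated alike. Of 8 probes lower in females 4 were above, with a median shift of -0.11 against -1.11, -1.86 and -0.69 for the others, so in that set it was not nearer to the females. A higher scale of the array is argued against as the whole cause, since other probes at the same level shifted by 0.351, with an upper quartile of 1.20, and a low-detection area on a high male array, since the 52 probes with no spot in one shifted by 1.18, with a lower quartile of 0.69. A female fish or female RNA in the pool cannot be told apart from a change in these males: outside low-detection areas the array showed a median of 6.77% of the female level (quartiles 0.0912% and 16.4%) over the 8 probes more than 16-fold higher in females and 29.3% (11.4% and 56.2%) over the 64 others. The share is relative to the female excess, so a general upward shift of the array gives larger shares where the female fold is smaller. These values therefore cannot decide whether 1 share holds for all probes. The quartiles also overlap, and the profile of the females is assumed. Of the named probes, chosen for the size of their difference, UF_Ppr_AF_115478 was at 4.43% (lowest over the female arrays 2.31%), UF_Ppr_AF_115272 at 9.11%, too high a share by an unknown amount since it was saturated on most female arrays, UF_Ppr_AF_117573 at 0.298% (highest 1.22%) and the dim UF_Ppr_AF_118394 at -0.529%. A stream effect on male livers rests on 1 pool and was not tested. Over the kept probes, the deviations of this array and of the female array of its stream from their group means correlated at 0.440. The pairs of the other streams were at -0.435 to 0.0234. Both arrays of a stream also lay at the same position on their slides, so this correlation cannot be put down to the stream alone.

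Over other splits of the samples, high against low in females gave 0 calls in all 35 splits, the real one included, and the highest other was 0. Every split reaches a real count of 0, so this count cannot decide anything about chance. Averaged over sexes, 4 of 100 drawn splits gave at least the real 215, and the highest other gave 963, several times the real count; among others it too exchanged low male replicate 2 with high male replicate 2, which points to a structure of the samples. Where whole streams changed class, both sexes together, 1 of 35 splits, the real one, gave as many and the highest other gave 10. This is the smallest share that 35 splits allow, so it argues against chance at this level without excluding it. It leaves open the low-detection areas that go with the low male arrays. For female against male averaged over classes 3 of 100 reached the real 276, with 392 as the highest other. Where the sexes were exchanged only within streams, however, 5 of the 64 splits reached it, and 5 of 64 reached the 4 calls found with the stream as a fixed block, with 991 and 634 as the highest others, so chance cannot be excluded for splits that keep the streams together. That highest split exchanged the sexes of high replicates 1 and 4, which puts the 6 arrays with at least 19.3% of spots in low-detection areas on 1 side, and points to a structure of the samples. In the high streams 3 of 35 splits gave at least the 3 probes found, with 4 as the highest other, so chance cannot be excluded. In the low streams the 10 splits are too few for a share under 0.05; the real count was 641 and the highest other 0. For the interaction 6 of 100 splits gave at least 169, with 818 as the highest other, and 3 of 35 did where whole streams changed class, with 716 as the highest other, so chance cannot be excluded; both are several times the real count and exchanged low male replicate 2 with high male replicate 2.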

How the results depend on the processing

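The percentile over all probes, the floor and the leaving out of areas or sets of arrays were chosen after seeing the data. High against low in females stayed at 0 calls under every alternative run, with 1 to 346 probes at an unadjusted p under 0.05. This includes leaving out the 3 low male arrays, or high female replicates 1 and 4. It also includes the authors' table as labelled, whose columns matched other arrays best, so its 0 adds no support. The other counts are given in the order high against low males (716), averaged over sexes (215), female against male averaged (276), in high streams (3), in low streams (641) and interaction (169). Median centring gave 203, 0, 19, 2, 220 and 0, and split the male calls into 108 higher and 95 lower (otherwise 690 and 26), the sex average into 15 and 4 (272 and 4) and the low stream calls into 98 and 122 (608 and 33). The authors' table as labelled gave 0 for all 6. Each of its columns matched another array best, so these counts do not show an effect of processing. No filter gave 6096, 65, 110, 2, 417 and 3453, with 5104 of the male calls lower in high streams and 3037 of the interaction calls above 0. Probes well above background on all 14 arrays gave 11, 4, 15, 0, 18 and 3, where 236 probes were tested. The percentile over all probes gave 366, 11, 33, 2, 305 and 40. The floor gave 462, 95, 166, 2, 406 and 98. Leaving out low-detection areas gave 28, 2, 32, 0, 69 and 1 of 2171 probes tested. Array weights moved males to 387 and low streams to 358. Quantile normalization moved female against male averaged to 162, high streams to 1 and the interaction to 107. Normexp moved the class average to 134 and low streams to 964, and split the male calls into 535 higher and 224 lower, the sex average into 206 and 83 and the low stream calls into 667 and 297. The 7 male arrays alone gave 395. Apart from fewer probes or arrays tested, the cause was not tested.

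Leaving out single arrays gave 391 to 1066 calls in males, 66 to 541 averaged over sexes, 118 to 628 for female against male averaged, 0 to 3 in high streams, 295 to 1002 in low streams and 70 to 466 for the interaction. In males the arrays that moved the count by over 1.5 times were low replicate 1 (391), high replicate 1 (406) and high replicate 3 (413). In low streams they were low male replicates 1 (296) and 2 (1002) and low female replicates 1 (346), 2 (321) and 3 (295). In high streams the count was 1 without low male replicate 1, high male replicate 2, low female replicate 2 or 3, or high female replicate 4, and 0 without high female replicate 2 or 3, high male replicate 1 or 4, or low male replicate 3. For the class average, sex average and interaction the counts were 541, 628 and 466 without low male replicate 2, 478, 598 and 413 without low male replicate 3, 77, 133 and 73 without high male replicate 1, 131, 137 and 100 without high male replicate 4, 75, 143 and 78 without low female replicate 1, 66, 118 and 70 without low female replicate 2, 90, 134 and 76 without low female replicate 3, 107, 156 and 85 without high female replicate 3, and 79, 146 and 96 without high female replicate 4. Without low male replicate 1 the sex average gave 149 and the interaction 79, without high male replicate 2 the class average gave 138 and the sex average 161, without high male replicate 3 the class average gave 90 and the interaction 71, and without high female replicate 1 the class average gave 141.

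With the stream as a random block (correlation -0.09) the high stream count was 1 and no other count moved by over 1.5 times. With the stream as a fixed block the counts were 4 for the sex average, 0 in high streams, 265 in low streams and 0 for the interaction. With the replicate number as a fixed block the class average gave 36. The slide or scan as a block was not run, since each sex lies on 1 slide, and the gene list alternatives were not run, since no probe was given a name.

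Over all settings and the named probes of a comparison, a call was lost 10 times in males, 42 for the class average, 27 for the sex average, 42 in high streams, 17 in low streams and 42 for the interaction. Only the authors' table reversed named probes: in females UF_Ppr_AF_105830 (-1.48) and UF_Ppr_AF_103236 (-1.46); in males UF_Ppr_AF_108387 (-0.50); for female against male averaged UF_Ppr_AF_115478 (-1.49), UF_Ppr_AF_117573 (-2.29), UF_Ppr_AF_103721 (3.20) and UF_Ppr_AF_114856 (1.13); in high streams UF_Ppr_AF_111380 (1.55), UF_Ppr_AF_103721 (0.66) and UF_Ppr_AF_118394 (-0.44); in low streams UF_Ppr_AF_108387 (-2.86), UF_Ppr_AF_107655 (-7.06), UF_Ppr_AF_104171 (3.95) and UF_Ppr_AF_100641 (1.64); for the interaction UF_Ppr_AF_107857 (-0.34), UF_Ppr_AF_109244 (-3.22), UF_Ppr_AF_108387 (3.00) and UF_Ppr_AF_111384 (2.62). These reversals, and the calls lost with that table, come from columns that each matched another array best. They therefore do not show how the processing moved the probes. Signal over background limits all values from the low male arrays.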

Other observations

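In classes of probes formed after the data were seen, over the 7 arrays with under 5% of spots in low-detection areas, probes whose identifiers hold AM were well above background on 18.5% of arrays on average (710 probes), against 46.3% for those with AF (14498 probes). Probes named by an assembled contig were detected on 50.3% of arrays (11862 probes) and those named by a public sequence number on 25.6% (3309 probes). The median GC content was 36.7% for the first of these and 45.0% for the second.

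Within groups, the rank correlation over kept probes between pairs of arrays was 0.858 to 0.903 in low females, 0.431 to 0.747 in high females, 0.479 to 0.938 in high males and 0.185 to 0.232 in low males.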
